A study of Drosophila melanogaster with 4 samples.

How the data were processed

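H3K9ac, the acetylated form of lysine 9 of histone H3 and a mark of active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from heads of wild-type Oregon-R Drosophila melanogaster. Per the labels, the flies were mixed adults grown in population cages, and heads were separated from bodies with sieves. There were 2 ChIP libraries and 2 input libraries, and each input served as the background for the ChIP library of the same replicate number. Chromatin was crosslinked with formaldehyde and sheared by sonication, per the labels' protocols. The labels do not say whether the replicates came from separate fly populations, so any spread between them may be technical.

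Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7. The authors deposited 3 lists of enriched regions, called clusters here, as positions in base pairs with 1 score per cluster: 1 list per ChIP replicate and 1 list for the whole series. Coordinates are those of FlyBase release 5, per the file headers, which also give the length of each of the 14 sequences. The scale of the deposited score is not given in the sources used here, so the score served mainly to rank clusters or compare sequences within a list. Correlations of scores between the replicate lists and means of median scores over them assume that both lists use 1 scale. The cluster caller, its thresholds, the read depth of the libraries and the way in which the replicates were joined in the whole-series list are not given in the sources used here. The depth behind each value is therefore unknown, and no interval that needs it was computed.

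The lists differed in construction. The shortest cluster measured 1301 bp in both replicate lists and 1001 bp in the whole-series list. All starts in the whole-series list (100%) were even numbers, against 50.2% in each replicate list. The whole-series list also held 1 region named as depleted, which was kept out of all counts of clusters. Scores of the whole-series list and of the replicate lists are printed side by side but were not tested against each other, since lists of different construction may use different scales.

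The lists were read as deposited, with no filter. The samples were grouped by their titles. The input libraries were not analysed on their own here, because they enter only through the clusters called against them. A cluster had a partner when at least 1 bp of it was covered by a cluster of the other replicate. The share of clusters with a partner and the Jaccard index (shared over total covered bases) were tested with a one-sided permutation test by 1000 random circular shifts of 1 list along each sequence, which keeps cluster lengths and spacing. The smallest p this test can give is 0.001. Exact Clopper-Pearson 95% intervals beside shares of clusters treat clusters as independent and cover counting error only. Correlations of scores and lengths were taken across pairs of clusters that overlapped each other and no other cluster. They describe the lists, since clusters are not replicates. Densities and covered shares used the sequence lengths of the headers, and means over the replicates are given with the SD (n = 2). No p-value was computed between chromosome arms, and their differences are given with the spread of the 2 replicates. Density ratios between the X and the large autosome arms (2L, 2R, 3L and 3R) carry exact 95% intervals conditional on the total count. Broad clusters were those of at least 10 kb.

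The permutation test was tested on simulated data. Of 40 simulated lists of 9104 clusters placed at random, 2 gave a p at or below 0.05 against replicate 1 with 200 shifts. Lists placed at random share no regional layout with replicate 1, so the test was not tried on lists that do. With 40% of the replicate 1 clusters planted in 10 simulated lists, the mean share recovered above chance was 40.2%. The chance level in this step came from the clusters known not to be planted, which are not known in real lists. This step therefore checked the counting of overlaps, not the shift means used for the real lists. The count of clusters with a partner was checked against bedtools 2.31.1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

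The tests, the named clusters and most alternatives were chosen before the data were examined. The rule for named clusters took the 10 highest-scoring and the 10 longest clusters of the whole-series list and, in each replicate, the 3 highest-scoring clusters without a partner. The alternatives were a larger minimum overlap, the upper 50% of each list by score, merging of clusters less than 500 bp apart, the major arms alone and each replicate list alone. The comparison of scores between the X and the autosomes, the windows along the arms, the shares under shifts for score deciles and broad clusters and the search for stretches without clusters were added after the lists had been seen. Tests of transcription start sites and of gene lists had also been planned. They need gene coordinates of release 5, while the gene table used here was of release 6, and coordinates were not converted between releases. Clusters are therefore given by position, with no gene names.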

Results

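The data were cluster lists of H3K9ac ChIP-seq from adult fly heads, with 1 list for each of 2 ChIP replicates and 1 list for the whole series. Heads are rich in neurons, photoreceptors, glia, fat body and muscle, and the lists describe the mixture of their nuclei. Replicate 1 held 9104 clusters that covered 30.5 Mb, and replicate 2 held 10049 clusters that covered 33.1 Mb. On the major arms (2L, 2R, 3L, 3R, 4 and X), these clusters covered 25.2% and 27.4% of the sequence. The whole-series list held 12182 clusters and covered 35.5% of the major arms. The read depth behind the clusters is unknown.

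The chromosomal distribution of the clusters was examined first. H3K9ac clusters lay almost entirely on the major arms, with 9044 of the clusters of replicate 1 and 9990 of those of replicate 2. Among the large autosome arms, the covered share was highest on 2R, at 29.6% ± 2.06 (SD, n = 2), and lowest on 3L, at 25.1% ± 1.40. The arm 3R had 28.4% ± 1.90 covered and 2L had 26.5% ± 1.92. These differences were of the order of the SDs, but replicate 2 had more cover on each of these arms, which widens the SDs. Within each of the 2 replicates, 2R had the highest and 3L the lowest covered share of these arms. The shares were 28.1% and 24.1% in replicate 1 and 31.1% and 26.1% in replicate 2. The X chromosome had 22.5% ± 0.532 covered, less than each large autosome arm in both replicates. Relative to the large autosome arms as a whole, the covered share of the X was 0.847 in replicate 1 and 0.798 in replicate 2. In the whole-series list this ratio was 0.902. The ratio of clusters per Mb was 0.931 in replicate 1, 0.905 in replicate 2 and 1.02 in the whole-series list. In the upper 50% of each list by score the ratio of covered shares was 1.06 in replicate 1, 0.984 in replicate 2 and 1.03 in the whole-series list. A cut on the score keeps more of the X, where scores were higher, so these values do not show which clusters the lower cover of the X rested on.

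The small chromosome 4, which carries genes within largely heterochromatic DNA, had 13.4% ± 1.14 of its sequence covered (SD, n = 2). Its covered share relative to the large autosome arms was 0.546 in replicate 1 and 0.441 in replicate 2. The number of clusters on chromosome 4 was 73 in replicate 1 and 68 in replicate 2, or 52.2 ± 2.62 per Mb against 80.6 ± 6.02 per Mb on the large autosome arms. The 6 scaffolds of centromere-proximal and Y heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) had 1.30% ± 0.00878 of their sequence covered. XHet had the highest covered share among them, at 6.37% ± 0.0970, and 3RHet the lowest mean, at 0.747% ± 0.0312. YHet held 2 clusters in replicate 1 and 1 in replicate 2. The unplaced sequence U had 0.274% ± 0.0608 covered, and Uextra held 0 clusters in all 3 lists. The header lists Uextra, but whether reads were aligned to it or kept there is not given in the sources used here. Mappability was not examined. Repeats to which reads cannot be assigned would also lower the covered share of these sequences and of the arm ends described next.

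**Figure D1:**
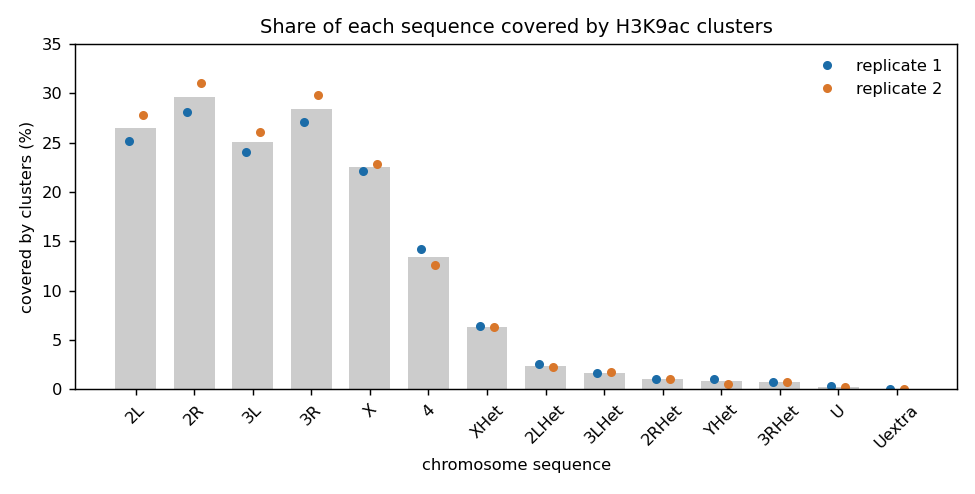
Share of each chromosome sequence covered by H3K9ac clusters, in percent, with a point per replicate and a grey bar at the mean of the 2 replicates. The bars of the large autosome arms and the X stand at 22.5% or more, that of chromosome 4 stands at 13.4% and those of the heterochromatin scaffolds stand at 6.37% or less.

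Along the arms, cover by H3K9ac clusters was much lower at the centromere-proximal end of 2L, 2R and 3L, and not of 3R. In the last 1 Mb of 3L, 1.91% of the sequence was covered in replicate 1 and 1.42% in replicate 2, against 25.03% and 27.1% of the rest of the arm. In the first 1 Mb of 2R, the covered share was 5.19% and 4.29%, against 29.3% and 32.4% of the rest. In the last 1 Mb of 2L it was 5.04% in each replicate, against 26.0% and 28.9%. On the X, 11.8% and 14.0% of the last 1 Mb was covered, against 22.6% and 23.3% of the rest. Low cover on the X was not specific to this end, since the window 3000001 to 4000000 had 15.2% and 15.7% covered. The first 1 Mb of 3R had 25.6% and 27.0% covered, against 27.2% and 29.9%. The heterochromatin scaffolds are separate sequences, and 3RHet had 0.747% ± 0.0312 covered (SD, n = 2). The values for the end of 3R therefore need not describe the sequence nearest its centromere.

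In both replicate lists, the highest cover in any full 1-Mb window of these 5 arms lay on 3L directly before the centromere-proximal drop. This window, positions 22000001 to 23000000, was covered to 41.1% in replicate 1 and 47.6% in replicate 2. The next window, positions 23000001 to 24000000, was covered to 2.68% and 2.12%. The next highest mean cover was in 2L 1000001 to 2000000, with 40.5% ± 5.38 (SD, n = 2), and in 2R 5000001 to 6000000, with 38.5% ± 1.69. In the whole-series list the order of the first pair was turned, with 55.5% on 2L and 55.1% on 3L. Across the 117 full windows, Spearman's rho between the replicates was 0.96, and 102 windows had more cover in replicate 2. Windows are not independent replicates.

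**Figure D2:**
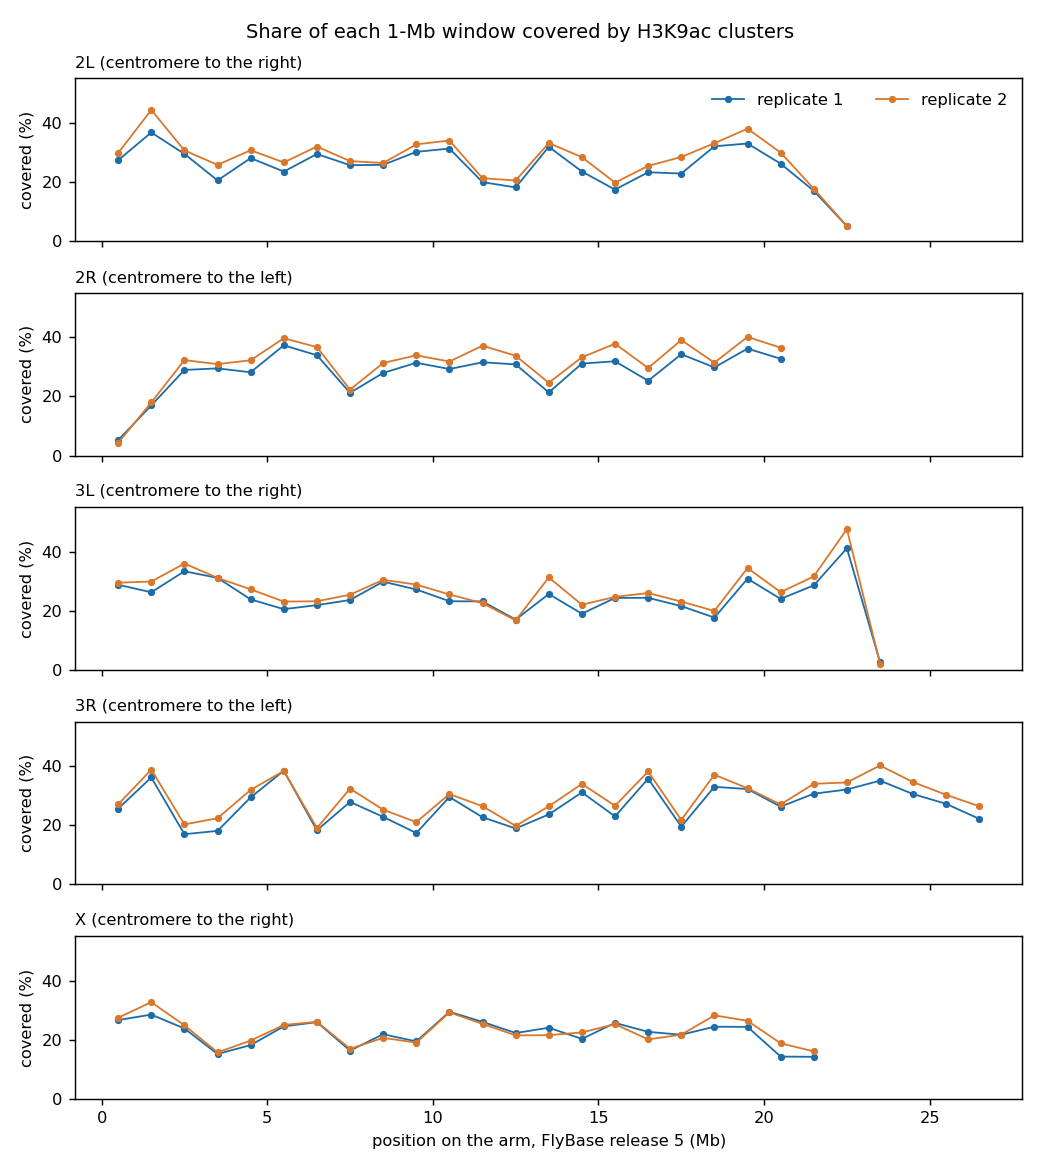
Share of each full 1-Mb window covered by H3K9ac clusters, in percent, against the position on the arm in Mb, with a line per replicate and a panel per arm. Cover drops at the centromere-proximal end of the arm sequence on 2L, 2R and 3L, to between 2.12% and 5.19%, and not on 3R.

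The replicates were then compared with each other. Of the replicate 1 clusters, 8295 (91.1%, exact 95% interval 90.5 to 91.7) had a partner in replicate 2. Of the replicate 2 clusters, 8231 (81.9%, 81.1 to 82.7) had a partner in replicate 1. Random circular shifts gave means of 45.8% and 42.0% and maxima of 52.0% and 47.2%, so that both shares were above all 1000 shifts (permutation p = 0.001, one-sided, the smallest possible). The replicates shared 27.2 Mb of covered sequence, which was 89.1% of that of replicate 1 and 82.0% of that of replicate 2. The Jaccard index was 0.745, against a mean of 0.152 and a maximum of 0.186 under shifts (permutation p = 0.001, one-sided).

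High-scoring clusters had a partner more often than low-scoring ones, by more than their greater length gave under shifts. In the highest score decile, 100% of the replicate 1 clusters and 99.9% of the replicate 2 clusters had a partner, against means of 48.3% and 45.3% under shifts. In the lowest decile the shares were 70.5% and 69.3%, against 39.5% and 36.0%. In replicate 2 the lowest share lay in the second decile, at 60.1% against 37.0%. Clusters without a partner, 809 in replicate 1 and 1818 in replicate 2, had median lengths of 1552 bp and 1641 bp, against 2706 bp and 2786 bp for those with one. All 241 broad clusters of replicate 1 and all 266 of replicate 2 had a partner, but shifts alone gave one to a mean of 74.7% and 70.6% of them and to at most 83.8% and 80.5%. All of these broad clusters were also covered to at least 50% by the other replicate. Under shifts this held for a mean of 21.1% and 18.8% of them and for at most 39.8% and 38.0%. Across 6795 clusters that overlapped one-to-one, the authors' scores had a Spearman's rho of 0.88 and a Pearson's r of 0.92, and the lengths had a rho of 0.84.

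**Figure D3:**
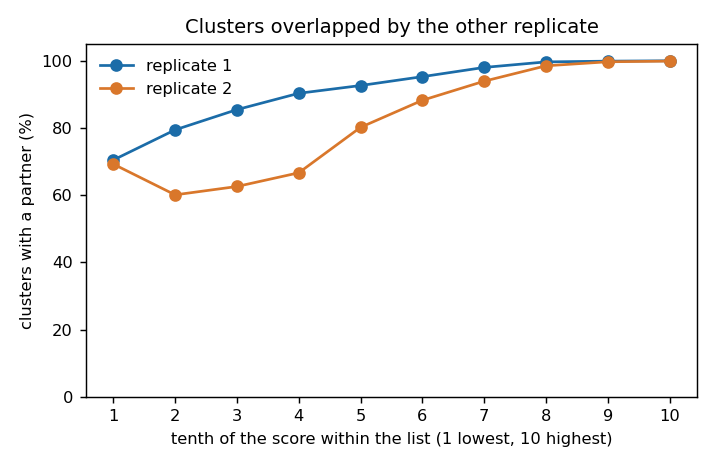
Share of clusters overlapped by a cluster of the other replicate, in percent, by decile of the authors' score within each replicate list. The share is 70.5% and 69.3% in the lowest decile and 100% and 99.9% in the highest, with a low of 60.1% in the second decile of replicate 2.

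The 3 highest-scoring clusters without a partner in each replicate measured between 1320 and 2731 bp. In replicate 1 they were U 7459483 to 7460861 with a score of 1.26, X 3623289 to 3625312 with 1.03 and X 19397076 to 19399806 with 1.01. In replicate 2 they were 2RHet 1730237 to 1731556 with a score of 1.28, 2R 6906214 to 6907841 with 1.11 and X 9988672 to 9990012 with 0.990. Each of these 6 clusters overlapped a cluster of the whole-series list.

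The whole-series list was compared with each replicate. It is not independent of them, and no test was made. It overlapped 9092 (99.9%) of the replicate 1 clusters and 10009 (99.6%) of the replicate 2 clusters. Of its own 12182 clusters, 7235 (59.4%) overlapped both replicates, 715 (5.87%) replicate 1 only and 1607 (13.2%) replicate 2 only. The remaining 2625 (21.5%) overlapped neither replicate. These had a median length of 1309 bp and a median score of 0.361, against 3507 bp and 0.680 for the clusters found in both. Of the 2625 clusters, 1276 (48.6%) were shorter than 1301 bp, the shortest length in the replicate lists.

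Of the 10 highest-scoring clusters of the whole-series list, 9 had a cluster in each replicate. The highest score, 3.11, belonged to U 7530986 to 7533132 on unplaced sequence, which scored 4.21 in replicate 1 and 2.21 in replicate 2. On the arms, the cluster with the highest whole-series score among those found in both replicates was 2R 12456968 to 12459662, of 2695 bp, with 2.54 in the whole-series list, 2.72 in replicate 1 and 2.38 in replicate 2. It was followed by 2L 8040266 to 8044964 with 2.51 and 2L 868510 to 873156 with 2.40. The latter had the highest score of the replicate 2 list, 2.41. The X contributed 20105288 to 20108334 with 2.29 and 6187462 to 6191946 with 2.22. The others were 2R 16150562 to 16153494 with 2.26, 2L 19007596 to 19010164 with 2.26 and 2R 10102432 to 10105010 with 2.19. The exception was 2L 21354012 to 21355014, of 1003 bp, which scored 2.69 in the whole-series list and overlapped no cluster of either replicate. Its length is below the shortest cluster of the replicate lists.

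Clusters were mostly a few kb long, with medians of 2534.5 bp in replicate 1 and 2449 bp in replicate 2. Broad clusters made up 2.65% of the clusters in each replicate and 11.5% and 11.9% of the clustered sequence. The longest cluster of the whole-series list, 3L 22128412 to 22200232, spanned 71.8 kb within the 3L window of highest cover in the replicates, and was split into 3 clusters in each replicate. The second, 2R 1690618 to 1740208, spanned 49.6 kb, as 2 clusters in replicate 1 and 1 in replicate 2. The others spanned 35.7 to 41.8 kb and lay on 3R (5 clusters), 2L, 2R and 3L (1 each), with none on the X or on chromosome 4. All 10 overlapped clusters of both replicates, and 2 of them, 3R 23225068 to 23264036 and 3L 21871864 to 21908820, were single clusters in each. Such overlap is no measure of agreement, since the whole-series list is not independent of the replicates. Long clusters also readily overlap others by at least 1 bp. Shifts alone gave a partner to a mean of 74.7% and 70.6% of the broad clusters of replicates 1 and 2. With at least 50% of the cluster covered, these means were 21.1% and 18.8%. Scores and lengths went together across clusters, with a Spearman's rho of 0.69 in replicate 1 and 0.70 in replicate 2.

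Clusters on the X were compared with those on the large autosome arms within each list. The X had a higher median score than each of the 4 large autosome arms in all 3 lists. Its median was 0.804 against 0.671 for these arms together in replicate 1, and 0.751 against 0.642 in replicate 2. Low-scoring clusters were scarce on the X. In the lowest score decile, replicate 1 had 1.43 clusters per Mb on the X and 8.90 per Mb on the large autosome arms, a ratio of 0.160 (exact 95% interval 0.109 to 0.228). In replicate 2 the ratio was 0.197 (0.142 to 0.268). In the highest decile the X had the higher density, with ratios of 1.496 (1.28 to 1.74) and 1.55 (1.34 to 1.79). The ratio did not rise steadily with the score. It was 1.46 and 1.51 in the sixth decile and 1.15 and 1.12 in the ninth. In the whole-series list it was 2.10 in the sixth decile, 1.01 in the eighth and 1.34 in the highest. Broad clusters were 1.25% and 1.04% of the X clusters, against 3.00% and 3.02% of those on the large autosome arms. Within the upper 50% of clusters by score the difference of medians was -0.01 in both replicates and -0.08 in the whole-series list. These subsets were cut on the score that is compared, so they are no test of the difference in the full lists. In the whole-series list the sign turned, from 0.08 in the full list, and whether the cut alone gives this was not tested. The sex make-up of the flies is not given in the sources used here.

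**Figure D4:**
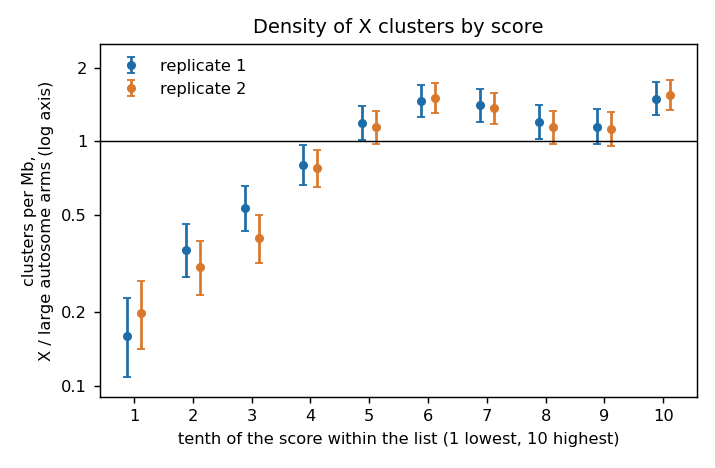
Clusters per Mb on the X divided by clusters per Mb on the large autosome arms (log axis), by decile of the authors' score within each replicate list, with exact 95% intervals that cover counting error only. The ratio is 0.160 and 0.197 in the lowest decile, 1.46 and 1.51 in the sixth, 1.15 and 1.12 in the ninth and 1.496 and 1.55 in the highest.

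The whole-series list named 1 depleted region, 4 106840 to 108430 on chromosome 4, with a score of -0.06. It was not named as depleted in either replicate list.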

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

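The overlap of the replicates kept its side of the threshold under all 5 alternatives (permutation p = 0.001 in each). The share of clusters with a partner lay between 80.4% and 91.3% for replicate 1 and between 72.8% and 82.4% for replicate 2, the lowest under a reciprocal overlap of 50%. For the reciprocal overlap, the shifts counted all clusters covered to at least 50%. This is an upper bound of the reciprocal share under shifts, so the p of that setting is conservative. The Jaccard index lay between 0.703 and 0.748 over 3 alternatives. Requiring 50% of a cluster to be covered moved the overlap with the whole-series list to 99.8% and 99.5%. Spearman's rho of the scores was 0.89 with a reciprocal overlap of 50% and unchanged to 2 decimals without the unplaced sequence U. Relative to the large autosome arms, the covered share in the whole-series list was 0.902 on the X, 0.422 on chromosome 4 and 0.0402 on the heterochromatin scaffolds. With each replicate list alone, it ranged from 0.798 to 0.847 on the X, from 0.441 to 0.546 on chromosome 4 and from 0.0453 to 0.0502 on the scaffolds. In the upper 50% of the whole-series list by score it was 1.03 on the X, 0.461 on chromosome 4 and 0.0497 on the scaffolds. In that of replicates 1 and 2, added after seeing the data, it was 1.06 and 0.984 on the X. The X minus autosome difference of median scores was 0.08 in the whole-series list and ranged from 0.109 to 0.133 with each replicate list alone. It reversed to -0.0812 in the upper 50% of the whole-series list, to -0.0135 in that of replicate 1 and to -0.00577 in that of replicate 2, alternatives chosen after seeing the data. That setting cuts on the score that is compared, so it is no test of the difference in the full lists. It also raises the covered share of the X by construction. Whether the cut alone turned the sign in the whole-series list was not tested. In that list the X over autosome density ratio was 2.10 in the sixth score decile and 1.01 in the eighth. The comparisons of transcription start sites and gene lists, with their alternatives, were not run, since no gene coordinates of release 5 were used here. No paired analysis was possible because the input libraries enter only through the clusters called against them, so that no test compared ChIP with input. With the read depth unknown, the larger number of clusters in replicate 2 cannot be set against its depth.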

Other observations

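The search for stretches without clusters, the comparison of scores between sequences and the test of clusters without a partner were chosen after the results had been seen. The other tests concern patterns noticed in these lists, and each was set before its own value was computed.

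The major arms held 39 stretches of at least 100 kb with no cluster in either replicate, of which 24 lay more than 2 Mb from the centromere-proximal end of an arm. Of the 9 stretches of at least 200 kb, which together measured 2.58 Mb, 3 lay that far from it. The longest was 3L 23334385 to 23707240, of 372.9 kb, followed by X 21502024 to 21845696, of 343.7 kb. The 3 that lay more than 2 Mb from that end were 3R 12480773 to 12811153 of 330.4 kb, 2R 2134360 to 2389177 of 254.8 kb and 3R 2676544 to 2891144 of 214.6 kb. The whole-series list placed 1, 3 and 2 clusters in these. A stretch of repeats to which reads cannot be assigned would also hold no cluster, and mappability was not examined.

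Clusters in heterochromatin were few but scored high. On the 6 heterochromatin scaffolds the median score was 1.12 ± 0.1998 (SD, n = 2), against 0.656 ± 0.0203 on the large autosome arms. On chromosome 4 the median score was 0.794 ± 0.111, and on U 0.972 ± 0.127. The medians rest on 45 clusters on the scaffolds in replicate 1 and 48 in replicate 2, where they were 1.26 and 0.974. Weak clusters missed on these sequences would also raise the median of those called, and this was not tested.

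The higher scores of X clusters had the same form in both replicates. The tables argue against different cluster lengths on the X, since the difference of median scores within deciles of length was 0.152 in replicate 2 and 0.158 in replicate 1 (bootstrap 95% intervals 0.136 to 0.168 and 0.137 to 0.177). Weak clusters missed on the X stay open: the highest score decile was 1.496 (1.28 to 1.74) and 1.55 (1.34 to 1.79) times as dense there in replicates 1 and 2, which missed weak clusters alone would not give, but the ninth decile had ratios of 1.15 (0.972 to 1.35) and 1.12 (0.959 to 1.31), and a higher density of clusters of every strength on the X, for which the test made no allowance, could lift the upper deciles too. One constant offset of all X scores also stays open, and it was examined in the replicate lists only. With 0.12 subtracted, the offset chosen in each replicate to give the flattest densities, the highest over the lowest density ratio across deciles was 1.33 in replicate 2 and 1.26 in replicate 1, under the limit of 1.5 set in advance. X scores drawn from the autosomal ones gave medians of 1.24 and 1.25, and the central 95% of their values ended at 1.44 and 1.39, so what was left after the offset was within sampling noise. The bootstrap 95% intervals (1.23 to 1.67 and 1.20 to 1.61) included the limit, and the offset was fitted to the scores it was tested on. No biological explanation was tested, since the design has no groups by sex.

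Clusters of 1 replicate with no partner had a median score percentile of 17.0 in replicate 1 and 25.3 in replicate 2, within their own list. In the whole-series list, 98.5% and 97.8% of them overlapped a cluster. The low percentiles restate the rise of the share with a partner across score deciles, so they decide nothing about weak clusters near the calling limit, and this and differences in depth between the libraries stay open.

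In replicate 2, clusters of the lowest score decile had a partner more often (69.3%) than those of the next 3 deciles (63.1%). Clusters of the lowest decile were not longer on the median, at 0.838 times the length in these 3 deciles (bootstrap 95% interval 0.822 to 0.856). A median cannot exclude a minority of broad clusters with a diluted score, so that explanation stays open. The median distance to the nearest cluster was 1.15 times as large in the lowest decile as in these 3 (0.965 to 1.33). This interval includes 1, so whether lowest-scoring clusters flank stronger clusters also stays open. In replicate 1 the share with a partner was lowest in the lowest decile, at 70.5%, and the difference between the replicates was not tested.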
